A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

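Gene expression in the yeast strains DJ28 and FY23 was measured on 10 arrays with 2 dyes, each array comparing the strains directly. Per the labels, DJ28 was labelled with Cy3 on arrays 1 to 5 and FY23 with Cy3 on arrays 6 to 10, and the arrays were grouped by this orientation. The deposited table of the authors holds 1 value per row and array, for 6277 rows, which was read as a log2 ratio of the 2 dyes. The scale was read from the values, of which 13 cells in 11 rows lie at an upper limit of 16.61. PDE2 has opposite signs in the 2 orientations, so the columns keep the direction of the dyes and were not turned to a common strain. Whether the ratio is red over green or green over red is not given in the sources used here. It was taken as red over green, the direction in which PDE2 is lower in DJ28. This direction is likely but not settled. Its basis is that the labels name PDE2 and the title an activated Ras/cAMP pathway, and that loss of PDE2 is known to raise cyclic AMP. It also takes DJ28 as the mutant and the change in it as a loss of PDE2, which the values alone cannot show. If the ratio is green over red, every statement of higher or lower, for strains and for dyes, turns together, while sizes, p-values and the grouping of genes that moved the same way stay as they are. The columns are not centred: the medians of arrays 1 to 10 are -0.085, -0.498, 1.383, 0.675, 0.854, 0.665, 0.198, 0.925, 0.633 and 0.604. The normalization, the background correction and the filter that left cells empty are not given in the sources used here. The arrays hold 2230, 4342, 5900, 6048, 5902, 5830, 5882, 6005, 5755 and 6030 values in the same order. No column of values was left unused.

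Rows were named through the platform annotation given with the series, in which 5663 rows have 1 gene symbol, 0 have several and 614 are not listed and stay unnamed here. Of the named rows 5659 matched the gene table of assembly R64 by gene identifier, and 4 kept the symbol of the annotation. That table was used for names only, and no coordinates are given because the build of the array is not named.

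Cells at the upper limit were set to missing, each array was centred on its median, and the rows of a gene were averaged. A gene was tested if it had a value on at least 3 replicates of each orientation, which held for 5642 genes or unnamed rows, 5144 of them named. The log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a dye term, equal on all arrays, and a strain term, positive where DJ28 was in Cy5 and negative where it was in Cy3. P-values are those of limma's two-sided moderated test, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A difference is the log2 ratio of DJ28 over FY23 throughout, and a turned value is an array's centred ratio with the sign set to that direction.

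The design fixed before the data were examined counted all 10 arrays. Arrays 6 and 7 were found to differ far less than any other pair, and their mean was used as 1 replicate. This departs from that design, and the fit with all 10 arrays counted apart is among the alternatives. Leaving out array 6 or array 7 alone leaves the other in its place, so the fit without both is the one that removes this replicate. The 4 arrays with cells at the upper limit (4, 5, 9 and 10) also shared their missing cells more with each other (r from 0.381 to 0.503) than with the remaining arrays (r from 0.084 to 0.254). No label gives a batch, and the remaining arrays, with r from 0.122 to 0.474 outside the pair 6 and 7, are not shown to form a single one. Fits within these 2 array sets, and fits with a dye effect in each, were made.

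The 43 gene lists were fixed before the data were examined. Each was tested with limma's camera test in its form for ranked statistics (cameraPR), on z-scores of the moderated statistic, because the table has empty cells, with a preset correlation of 0.01 and adjustment over the 43 lists. The correlation was also estimated for each list, and the fry test run, on 4982 genes with a value on each of arrays 3 to 10. A negative estimate was taken as no correlation.

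Named genes followed a rule fixed before the data were examined. It takes PDE2 and other pathway members past the test, the 12 largest positive and 12 largest negative differences among genes past the test with the same sign on every array, and up to 4 members past the test with the largest absolute difference in each list described. Members of the marker and mating-type lists are given whether or not they passed. Unnamed rows stay unnamed.

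The steps were tested on simulated data with 9 replicates and 5642 genes, of which 200 were changed. Of the 1.5-fold changes 66.7% were called, of the 2-fold changes 86.2% and of the 4-fold changes 98.5%. Of 171 calls 4 were false. A shifted list was called and 0 unshifted lists were. The simulated noise was independent between genes and held no array sets. False calls of lists whose genes move together, as in the real data, were therefore not tested by it.

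Alternatives to centring, scaling, the dye term, the minimum number of arrays, the estimate of the spread, array weights, the handling of rows of a gene, the arrays used and the list test were fixed before the data were examined. The scaled alternative used limma's scaling to equal median absolute values in place of the function first named for it, which gave no values on centred columns. Others were added after the data were seen: arrays 6 and 7 apart or left out, arrays 1 and 2 left out, the upper limit kept, fits by array set, unnamed rows left out and lists without shared members. The test by splits of the replicates that keep the shares of the array sets was also added then. In the tests of technical explanations, the test of cross-hybridisation among acid phosphatase genes and the test of dye bias between the array sets were each rewritten after the results had been seen, because the first versions could not decide the question.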

Results

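Gene expression was compared between 2 strains of the yeast Saccharomyces cerevisiae, DJ28 and FY23, on 10 spotted arrays with 2 dyes. The title of the series describes a mutant with an activated Ras/cAMP pathway, the signalling route through which glucose raises cyclic AMP and protein kinase A activity in yeast, and the labels give PDE2 as a keyword. Each array held both strains. On arrays 1 to 5 DJ28 was labelled with Cy3 and FY23 with Cy5, and on arrays 6 to 10 the dyes were swapped. Arrays 3 to 10 had between 5755 and 6048 values for the 6277 rows, while array 1 had 2230 and array 2 had 4342. Arrays 6 and 7 correlated at r = 0.988 over all rows, against at most 0.694 for any other pair, and the SD of their difference was 0.125 against at least 0.423 for any other pair. Their mean was counted as 1 replicate, which left 9 replicates, 5 with DJ28 in Cy3 and 4 with DJ28 in Cy5. The labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.131.

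PDE2 (YOR360C), which encodes the high-affinity cyclic AMP phosphodiesterase, differed 3.89-fold between the strains and is given here as lower in DJ28. The sources used here do not give which dye is the numerator of the ratio. The direction in which PDE2 is lower in DJ28 was taken as the likely one, since the labels name PDE2 and loss of this gene is known to raise cyclic AMP. This choice takes DJ28 as the mutant and the change in it as a loss of PDE2. The size of the PDE2 difference was therefore measured and its direction was not, and every higher and lower below would turn together under the opposite direction. Its log2 difference was -1.96 with a standard error of 0.168 (limma, adjusted p = 0.00153), and it had the same sign on 8 of the 8 replicates that had a value. The mean was -1.75 with DJ28 in Cy3 and -2.17 with DJ28 in Cy5. Which part of the gene the spot covers is not given in the sources used here. No label gives a batch. In the values, arrays 4, 5, 9 and 10 stood apart from the remaining arrays: each had values at the upper limit of the scale, and they shared missing cells with each other at r from 0.381 to 0.503, against 0.084 to 0.254 with the remaining arrays. Among the remaining arrays, arrays 6 and 7 as a pair left aside, that r ran from 0.122 to 0.474, so they are not shown to form a single batch. Values are given below within each of these 2 array sets, first arrays 4, 5, 9 and 10 and then the remaining arrays, and each set holds both dye orientations. The PDE2 difference was -1.86 (adjusted p = 0.0339) and -2.06 (adjusted p = 0.171) within the array sets. With the arrays that had DJ28 in Cy3 alone, the adjusted p was 0.115.

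Between the strains, 31 of 5642 tested genes differed in limma's moderated test, 5 higher and 26 lower in DJ28. The 5 genes that differed at least 2-fold were all lower: HSP26 and HSP12, which encode small heat-shock proteins, HSP30, which encodes a plasma membrane protein induced by stress, PUT4, which encodes a proline permease, and PDE2. HSP26 was 5.94-fold lower, with a log2 difference of -2.57 and a standard error of 0.291 (adjusted p = 0.00483, lower on 8 of 8 replicates). PUT4 was 2.80-fold lower, at -1.49 with a standard error of 0.165 (adjusted p = 0.00436, 9 of 9). HSP12 was 2.19-fold lower (adjusted p = 0.0337, 8 of 8) and HSP30 was 2.16-fold lower (adjusted p = 0.0116, 8 of 8). The genes higher in DJ28 were PHO5, PHO12, PHO11 and PHO3, which encode acid phosphatases, and FRE7, which encodes a putative metal reductase. PHO5 was 1.85-fold higher, at 0.89 with a standard error of 0.107 (adjusted p = 0.00483, higher on 9 of 9 replicates), and FRE7 was 1.84-fold higher, at 0.88 with a standard error of 0.135 (adjusted p = 0.0252, 7 of 7). Of the 31 genes, 27 had the same sign on every replicate with a value, and 1 lies on a row with no gene name.

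Other settings moved the counts of 5 higher and 26 lower genes to 30 and 126 with array weights, to 14 and 65 with all 10 arrays counted apart, and to 0 and 4 with no centring of the arrays. From 31 genes in all, 3 passed a test against a 1.2-fold change, 0 passed with only the arrays that had DJ28 in Cy3 and 2 with only those that had DJ28 in Cy5. The count of 31 genes also depended on single arrays: it was 19 without array 2 (1 higher, 18 lower), 79 without array 8 (8 and 71), 12 without array 9 (2 and 10) and 10 without array 10 (1 and 9), and without array 5 the 5 higher genes were 3. Without array 10 the genes at least 2-fold apart were 3. Without the sparse arrays 1 and 2 it was 6 (0 higher, 6 lower), and without arrays 6 and 7 it was 17 (1 higher, 16 lower). PDE2, HSP26, PUT4, PGM2, YGP1, TSL1, GPD1 and PHO5 passed the test with any single array left out, and also without arrays 6 and 7 together, the pair counted as 1 replicate. The other named genes past the test each lost the call without at least 1 array: HSP30 without array 10, FRE7 without array 2, HSP12, FET3, JEN1, GUT2, GUT1, TPS2 and ACO1 without array 9 or 10, and PRB1 and YCL042W without array 2, 3, 9 or 10, the latter also without array 5. GAC1 lost it without array 2, 5, 9 or 10. Without arrays 6 and 7 together HSP12, GUT2, ACO1, GAC1, PRB1, YCL042W, PHO3, PHO11 and PHO12 lost the call, and FRE7 had too few values for the test, as it had without array 9 or 10. Without arrays 1 and 2 together no higher gene passed, so PHO5 did not hold there. The genes that passed with any single array left out thus did not all pass without these 2 arrays. Within arrays 4, 5, 9 and 10 alone 30 genes passed, 13 of them among the 31, and within the remaining arrays 0 passed. With the dye effect fitted in each array set the count was 37, which held all 31. A split of the replicates by array set, in place of the dye orientation, called 155 genes. Over the 59 other splits that keep the shares of the array sets, at most 5 genes passed. At an unadjusted p under 0.05 there were 753 genes, where 282 would pass by chance.

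**Figure D1:**
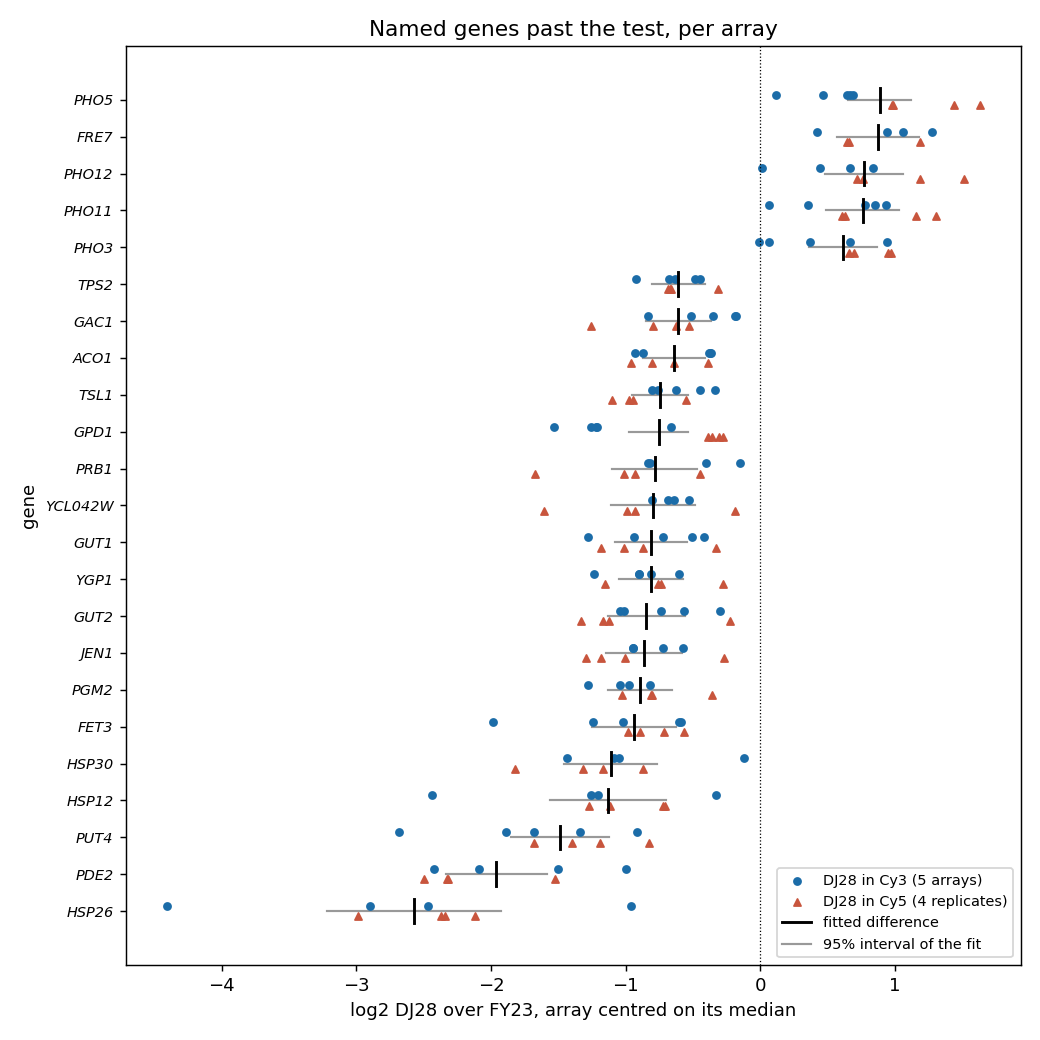
The plot shows the named genes past the test, with the log2 ratio of DJ28 over FY23, in the likely direction, on the horizontal axis after centring each array on its median, circles for the 5 arrays with DJ28 in Cy3, triangles for the 4 replicates with DJ28 in Cy5, black bars for the fitted difference and grey lines for its 95% interval. HSP26, at -2.57, and PDE2, at -1.96, lie farthest below 0, and PHO5, at 0.89, lies farthest above it.

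The list of genes with stress-response elements and the list of trehalose and glycogen metabolism were lower in DJ28. In the first list, that of genes with promoter sites bound by the transcription factors Msn2 and Msn4, 8 of 44 tested members fell over all genes tested and 20 adjusted over the list alone, and no member rose past the test either way. Of the 44 differences 33 were negative and 11 positive. The largest differences past the test were those of HSP26, HSP12, PGM2 at -0.89 and YGP1, which encodes a secreted glycoprotein, at -0.81. The median of the list was -0.28, it was below 0 on 9 of 9 replicates, and limma's camera test gave an adjusted p of 1.81e-13 (adjusted p = 0.000109 with an estimated correlation). Among genes of trehalose and glycogen metabolism, 4 of 18 fell over all genes tested and 11 adjusted over the list alone. They were PGM2, which encodes phosphoglucomutase, TSL1 at -0.75 and TPS2 at -0.61, which encode subunits of the trehalose synthase complex, and GAC1 at -0.61, which encodes a phosphatase subunit that acts on glycogen synthase. The median of that list was -0.45, below 0 on 9 of 9 replicates (camera adjusted p = 2.31e-12, and adjusted p = 0.00698 with an estimated correlation). Within the array sets the medians were -0.30 and -0.28 for the stress list and -0.40 and -0.42 for the storage list. The separate list of oxidative stress defence had 0 of 20 members past limma's test over all genes or adjusted over the list alone, 14 positive differences and a median of 0.09, and did not pass (camera adjusted p = 0.214).

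The list of gluconeogenesis and the glyoxylate cycle was also lower. Among genes of gluconeogenesis and the glyoxylate cycle, 1 of 16 members fell over all genes tested, JEN1, which encodes a lactate and pyruvate transporter, at -0.87 with a standard error of 0.127 (adjusted p = 0.0127, lower on 8 of 8 replicates). Adjusted over the list alone, 8 fell, and the 16 differences were all negative, with a median of -0.38 (camera adjusted p = 2.85e-09, and adjusted p = 0.000273 with an estimated correlation). The medians were -0.43 and -0.29 within the array sets. Lists for other carbon sources did not pass: galactose utilisation had 0 of 8 members past limma's test and a median of -0.14 (camera adjusted p = 0.101), and fatty acid beta-oxidation had 0 of 15, with 1 higher and 1 lower adjusted over the list alone, and a median of -0.06 (camera adjusted p = 0.272). Among genes of osmotic stress and glycerol metabolism, 3 of 20 members fell: GUT2 at -0.85 and GUT1 at -0.81, which encode enzymes of glycerol breakdown, and GPD1 at -0.76, which encodes an enzyme of glycerol synthesis. Adjusted over the list alone 7 fell. The list median was -0.22 (camera adjusted p = 3.21e-06), and its call was lost with adjusted p = 0.0531 with an estimated correlation. Its medians were -0.29 and -0.12 within the array sets. GPD1 also carried a dye effect of 0.42, with means of -1.18 with DJ28 in Cy3 and -0.33 with DJ28 in Cy5.

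In the list of the Ras/cAMP/PKA pathway itself, PDE2 was the only 1 of 18 members to pass over all genes tested, and also adjusted over the list alone. Of the 18 differences 15 were negative, with a median of -0.16, below 0 on 9 of 9 replicates (camera adjusted p = 0.000149, and adjusted p = 0.00445 with an estimated correlation). Without PDE2, a subset chosen after the data were seen, the other 17 members had a median of -0.16 (camera adjusted p = 0.00231, and adjusted p = 0.0401 with an estimated correlation). The medians of the whole list were -0.25 and -0.08 within the array sets. On genes with a value on all 10 arrays the list had a median of -0.164 and did not pass (camera adjusted p = 0.194).

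Several lists held a few lower genes each. In the list of nitrogen catabolite genes and amino acid permeases, PUT4 alone of 29 members fell over all genes tested and 4 fell adjusted over the list alone. The median was -0.19 (camera adjusted p = 2.26e-06, lost with adjusted p = 0.0769 with an estimated correlation), and -0.25 and -0.14 within the array sets. In the iron regulon, FET3, which encodes a multicopper oxidase of iron uptake, alone of 25 members fell over all genes tested, by 0.94 on the log2 scale (standard error 0.142, adjusted p = 0.0116, lower on 9 of 9 replicates), and 3 fell adjusted over the list alone. The median was -0.11 (camera adjusted p = 0.00128, lost with adjusted p = 0.0889 with an estimated correlation), and -0.16 and -0.09 within the array sets. It was -0.067 without array 3, -0.073 without array 4 and -0.074 without array 7. The call was lost with only the arrays that had DJ28 in Cy3 (-0.034, adjusted p = 0.317) and within the remaining arrays alone (adjusted p = 0.0837). Among heat-shock proteins and chaperones HSP26 and HSP30 fell, 2 of 25 members, and 6 fell adjusted over the list alone. The median was -0.11 (camera adjusted p = 0.0015, lost with adjusted p = 0.31 with an estimated correlation), and -0.20 and -0.09 within the array sets. It was -0.048 without array 3, -0.059 without array 10 and -0.166 without array 8. The call was lost on genes with a value on all 10 arrays (-0.114, adjusted p = 0.194), with only the arrays that had DJ28 in Cy5 (-0.018, adjusted p = 0.52) and within the remaining arrays alone (adjusted p = 0.0866). The 19 members outside the stress list had a median of -0.09 and did not pass (camera adjusted p = 0.0648).

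In the list of the phosphate regulon, 4 of 21 members rose both over all genes tested and adjusted over the list alone: PHO5, PHO12 at 0.77, PHO11 at 0.76 and PHO3 at 0.61. PHO3 also belongs to the list of thiamine and vitamin B6 synthesis, where it was the only 1 of 23 members to rise over all genes tested. It is therefore not a mark of the phosphate list alone. PHO3, PHO5, PHO11 and PHO12 are closely related in sequence, and the spots of these genes are open to cross-hybridisation. The median of the list was 0.07 (camera adjusted p = 0.0492, lost with adjusted p = 0.0767 with an estimated correlation), and 0.11 and 0.07 within the array sets. The call was lost without array 1, 2, 4, 7, 8 or 10, with adjusted p from 0.052 to 0.0983, and the median was 0.037 without array 2, 0.001 without array 4, 0.128 without array 5, 0.02 without array 8 and 0.1 without array 10. Without arrays 6 and 7 together it was 0.13 and the list passed (adjusted p = 0.00352). Over 29 alternatives to the arrays, genes and fit used, the call was lost in 14. With only the arrays that had DJ28 in Cy5 the median was -0.10 (camera adjusted p = 0.603). The list passed with only the arrays that had DJ28 in Cy3 (median 0.317, camera adjusted p = 0.00854). It also passed on genes with a value on all 10 arrays (0.382, adjusted p = 0.0127). Of the genes that rose, PHO3 lost its call without array 1, 2, 5, 8, 9 or 10, PHO12 without array 2, 5, 9 or 10 and PHO11 without array 2 or 10. The other 17 members had a median of 0.04 (camera adjusted p = 0.888).

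Among genes of ribosome biogenesis, 0 of 85 members passed over all genes tested or adjusted over the list alone (limma), and 62 differences were positive. The median was 0.09, above 0 on 8 of 9 replicates (camera adjusted p = 0.00703, and adjusted p = 0.00698 with an estimated correlation), and 0.07 and 0.13 within the array sets. The estimate was 0.006, below the preset 0.01, so the test with it was no stricter for this list. The call was lost without array 4 (median 0.088, adjusted p = 0.0695), with only the arrays that had DJ28 in Cy5 (median 0.119, adjusted p = 0.061) and within the remaining arrays alone (median 0.131, adjusted p = 0.0876). Of the 133 genes of cytosolic ribosomal proteins 0 passed either way, and 127 differences were positive, with a median of 0.26 (camera adjusted p = 1.81e-13, lost with adjusted p = 0.357 with an estimated correlation). The list median differed in sign between the dye orientations, with a mean of -0.35 over the arrays with DJ28 in Cy3 and 0.87 over those with DJ28 in Cy5, and it was above 0 on 5 of 9 replicates. It was 1.632 on the mean of arrays 6 and 7, against at most 0.85 on any other replicate, and without these arrays the median of the list was 0.131 (camera adjusted p = 3.59e-07). With the arrays that had DJ28 in Cy3 alone, the list passed in the opposite direction, at -0.32 (camera adjusted p = 5.05e-19). That fit has no dye term, so its value holds the dye effect of the list along with the strain difference. Its medians were 0.19 and 0.37 within the array sets. The list of mitochondrial ribosomal proteins had 0 of 55 members past the test and a median of 0.18 (camera adjusted p = 2.99e-05, lost with adjusted p = 0.238 with an estimated correlation), and 0.07 and 0.24 within the array sets. It was 0.111 without arrays 6 and 7 together, and the call was lost with only the arrays that had DJ28 in Cy3 (0.09, adjusted p = 0.485) and on genes with a value on all 10 arrays (0.092, adjusted p = 0.0864). The seripauperin family, a group of subtelomeric genes of near-identical sequence, had 0 of 22 members past the test and 22 positive differences, with a median of 0.23 (camera adjusted p = 3.81e-06, lost with adjusted p = 0.185 with an estimated correlation), and 0.24 and 0.27 within the array sets.

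**Figure D2:**
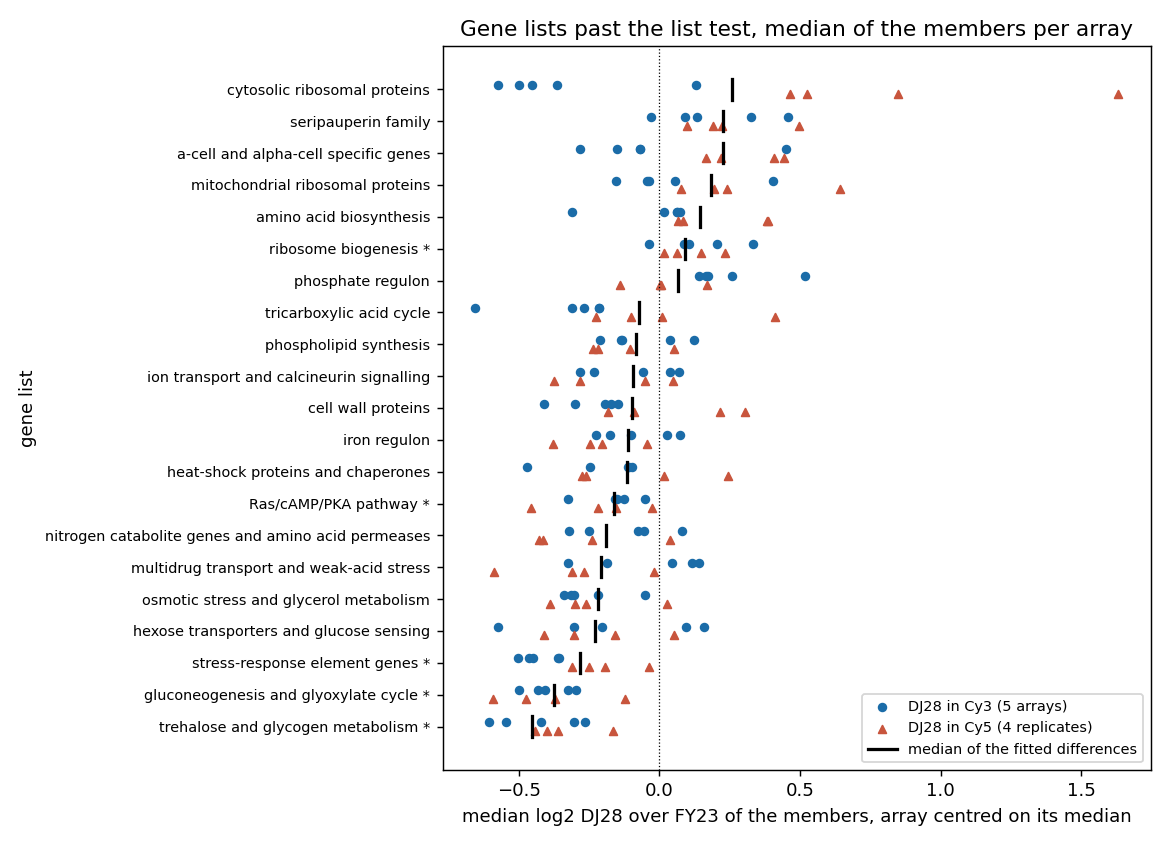
The plot shows the 21 lists past the camera test, with the median log2 ratio of DJ28 over FY23 of the members, in the likely direction, on the horizontal axis after centring each array on its median, circles for the 5 arrays with DJ28 in Cy3, triangles for the 4 replicates with DJ28 in Cy5, black bars for the median of the fitted differences and asterisks for the 5 lists that also passed with an estimated correlation. The stress and storage lists lie below 0 on 9 of 9 replicates, and the list of cytosolic ribosomal proteins lies above 0 on 5 of 9.

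Over all 43 lists tested, 21 passed camera with the preset correlation, 7 higher and 14 lower in DJ28. With a correlation estimated for each list, 5 passed: the stress-response, storage, gluconeogenesis and Ras/cAMP/PKA lists were lower and ribosome biogenesis was higher. By fry 9 passed: the stress-response, storage, gluconeogenesis, Ras/cAMP/PKA, nitrogen, osmotic, hexose and iron lists were lower and the phosphate list was higher. Ribosome biogenesis did not pass fry (adjusted p = 0.0649). Of the 21 lists, 19 had medians of the same sign in both array sets and 16 in both dye orientations. Camera with the preset correlation called a median of 8 lists over 99 other splits of the 9 replicates, and up to 22. Over the 59 splits that keep the shares of the array sets the median was 6 lists and the highest 20.

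The auxotrophic marker genes and the genes specific to a or alpha cells were examined as signs of other differences between the strains. Of the 7 marker genes 0 passed over all genes tested or adjusted over the list alone (limma). Their log2 differences were 0.37 for LEU2, 0.35 for URA3, 0.32 for ADE1, 0.29 for HIS3, 0.13 for MET17, 0.01 for ADE2 and -0.42 for LYS2, and the list did not pass (camera adjusted p = 0.12). Of the 10 genes specific to a mating type 0 passed over all genes tested, and MFA1 at 0.61 and MFA2 at 0.50, which encode the a-factor pheromone, passed adjusted over the list alone. AGA2 had a difference of 0.39, STE2 0.29, ASG7 0.24, BAR1 0.21, STE6 0.01, STE3 -0.0035, MF(ALPHA)1 -0.05 and SAG1 -0.16. Genes of a cells and of alpha cells are pooled in this list, so a test for 1 shared direction cannot test for a mating-type difference. The list had a median of 0.23 (camera adjusted p = 0.0406, lost with adjusted p = 0.0767 with an estimated correlation), and 0.15 and 0.32 within the array sets, and its call was lost without array 1 (median 0.203, adjusted p = 0.1), array 3 (0.295, adjusted p = 0.0718) or array 4 (0.247, adjusted p = 0.0512). Over the 29 alternatives the call was lost in 11, and the list turned with only the arrays that had DJ28 in Cy3 (-0.018, adjusted p = 0.564). MFA1, MFA2 and AGA2 carried dye effects, and each was negative on average with DJ28 in Cy3 and positive with DJ28 in Cy5.

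A dye effect, the part of the ratio, read as red over green, shared by both orientations, passed the test for 172 genes, 159 with higher red signal and 13 with lower red signal than the array median. Among the 31 genes that differed between the strains, 1 carried such an effect, GPD1.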

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

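In this part, the tests of the glycolysis list, of the residuals of the acid phosphatase genes, of the rest of the phosphate regulon, of the dye effect within the array sets and of splits that keep the shares of these sets were chosen only after the results they bear on were seen. Higher and lower are given in the direction of the ratio in which PDE2 is lower in DJ28, and would turn together under the opposite one. The array sets are arrays 4, 5, 9 and 10, which have values at the upper limit, and the remaining arrays.

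On the arrays with DJ28 in Cy5, the turned value of TPS2 was -0.31 on array 8, where the other 3 replicates lay between -0.68 and -0.67. LYS2 was at 0.052 on array 8, where the others lay between -0.87 and -0.75. These 2 came from 79 groups of values tested for a sample far from the others, and chance gives about 1 in 20. Among 40 named genes, 4 differed between the dye orientations in limma's test of the dye effect. The dye effect was 0.42 for GPD1 (adjusted p = 0.0464, means of -1.18 and -0.33 with DJ28 in Cy3 and in Cy5), 0.91 for AGA2 (adjusted p = 0.0286, -0.52 and 1.30), 0.82 for MFA1 (adjusted p = 0.0409, -0.21 and 1.42) and 0.69 for MFA2 (adjusted p = 0.038, -0.19 and 1.19).

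Genes of cytosolic ribosomal proteins had a median log2 difference of 0.26, and of 0.131 without arrays 6 and 7, which count as 1 replicate. The 17 genes with no A or B copy had a median of 0.237, against 0.258 for the 116 with a copy, and 0.135 without arrays 6 and 7. The pattern was thus not confined to genes with a copy, which argues against cross-hybridisation between paralogs as its whole source. The standard errors of 0.237 and 0.135 over genes were 0.034 and 0.025. They treat genes that move together as independent (estimated correlation 0.606 for the list), so they do not show that the median differs from 0 over arrays. Dye bias stays open: the turned list median was above 0 on 5 of 9 replicates, below 0 on 4 of the 5 arrays with DJ28 in Cy3 and above 0 on the 4 with DJ28 in Cy5, so a dye effect of unequal size between arrays may leave such a median. A bias of abundant transcripts also stays open, since the glycolysis list had a median of 0.009 with a standard error of 0.066, which does not exclude 0.129, the value at 0.5 of the ribosomal median; without arrays 6 and 7 it was -0.011 with 0.053, against 0.066. A difference between the strains stays open and was not tested apart from these.

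The 4 acid phosphatase genes PHO3, PHO5, PHO11 and PHO12 had a median difference of 0.76. Their mean was above 0 on 9 of 9 replicates, and so in both dye orientations. The 4 genes were chosen for passing a strain test fitted with a dye term, which left little room for another outcome. No conclusion on dye bias is drawn from it. The other 17 members of the phosphate list had a median of 0.037 with a standard error of 0.053. Without arrays 6 and 7 it was 0.089 with 0.062, where the 4 genes had 0.693. These values argue against a rise of the whole list as large as that of the 4 genes. The 17 are the members that did not pass, which lowers their median. Cross-hybridisation cannot be told apart from a shared response: the mean correlation of the residuals of the 4 genes was 0.686, between the bounds set for a single shared signal and for independent spots. A strain difference in 1 of these genes, read by the spots of all 4, may therefore give the pattern.

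The count of 31 genes was matched or passed in 4 of 100 drawn splits of the 9 replicates, the real one included, from 126 possible. The highest other split called 155 genes, several times the real count, and it separates exactly the 4 arrays with values at the upper limit from the rest; the other 2 splits above the real one, with 120 and 75 genes, differ from it by the place of a single sparse array. This points to a structure of the samples by array set, which such splits do not hold fixed. Each array set holds both dye orientations, so a dye bias that differs between the sets largely cancels in the strain term. With the dye effect fitted in each set 31 of the 31 genes were called, an outcome that this design left little room to change. It is thus the design, more than this fit, that argues against such a bias as their source. A dye bias that varies between arrays within a set was not tested. Over these 100 splits the share was under 0.05 for the count, the 5 higher genes (3 splits, highest other 148), the 26 lower genes (3 splits, highest other 120), the 5 genes at least 2-fold apart (4 splits, highest other 36) and the 21 lists (3 splits, highest other 22), where 21 of the 99 others called 15 or more lists.

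The 60 splits that keep the shares of both array sets were counted apart, the real one included. With 1 dye effect, 1 split called as many genes as the real 31 (highest other 5) and 1 as many lower genes as 26 (highest other 0). For genes at least 2-fold apart, 1 split called as many as 5 (highest other 3). Chance is thus less likely for these counts, by a bound of 3 in 60 splits set after the results were seen. For the 5 higher genes and the 21 lists, which also met that bound, these splits do not settle the question. The higher genes were matched by another split (2 splits, highest other 5), and the lists nearly so (1 split, highest other 20). The split that matched the higher genes sets arrays 2, 3, 4 and 5 against the rest, and it also called 20 lists. It is the real split turned round with array 1 misplaced. It thus holds much of the strain difference with its sign reversed, and its counts are no measure of chance. With the dye effect fitted in each set, 1 split called as many genes as the real 37 (highest other 8) and 1 as many lower genes as 32 (highest other 2). For genes at least 2-fold apart, 1 split called as many as 5 (highest other 3), and chance is again less likely for these counts. The question is not settled for the 5 higher genes of that fit, which 2 splits matched or passed (highest other 6). Nor is it settled for the 19 lists of that fit, which 3 splits matched or passed (highest other 21). The split of arrays 2, 3, 4 and 5 gave each highest other value of that fit, so these values also hold the reversed strain difference. The remaining arrays are not shown to form a single batch, and splits within a finer grouping of them were not run.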

How the results depend on the processing

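The alternatives named here for all 10 arrays apart, for array sets, for arrays 1 and 2 or 6 and 7 left out, for the upper limit kept and for unnamed rows were chosen after the data were seen, and the rest before. In the direction taken for the ratio, the PDE2 difference stayed below 0 in every fit that gave a value; the fit on genes with a value on all 10 arrays gave none, because PDE2 had too few values. Of 630 list results under the alternatives 545 kept direction and side of the threshold, 81 lost the call and 4 turned direction, and of 1093 results of single named genes 887 did, 173 lost the call and 33 turned. The turned genes were all uncalled markers or mating-type genes. Signal over background is not given in the sources used here, and the number of arrays limits these results.

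The main counts were 31 genes, 5 higher, 26 lower, 5 at least 2-fold apart, and 21 lists. With no centring 4 genes passed, 0 higher and 4 lower, and the genes with a dye effect went from 172 to 3041. Quantile normalization gave 12 genes at least 2-fold apart, and no dye term gave 3 higher genes. On genes with a value on all 10 arrays 2 were at least 2-fold apart, where 2039 genes were tested. Array weights gave 156 genes, 30 higher and 126 lower, with 12 at least 2-fold apart, and held all 31. Testing against a 1.2-fold change left 3 genes. With only the arrays that had DJ28 in Cy3, 0 genes passed, 0 higher, 0 lower and 0 at least 2-fold apart, and PDE2 was -1.753 (adjusted p = 0.115); with only those that had DJ28 in Cy5, 2 passed, 0 higher and 2 lower, both at least 2-fold apart (2). These 2 fits use fewer arrays and have no dye term, so their values hold the dye effect along with the strain difference. With all 10 arrays counted apart 79 genes passed, 14 higher and 65 lower. Only the arrays with values at the upper limit gave 12 higher genes and 12 at least 2-fold apart. Only the other arrays gave 0 genes, 0 higher, 0 lower and 0 at least 2-fold apart, PDE2 at -2.059 (adjusted p = 0.171), and 13 lists. Over all alternatives that gave a value the adjusted p of PDE2 ran from 0.000254 to 0.171. Without arrays 6 and 7 there were 17 genes, 1 higher and 16 lower, and without arrays 1 and 2 there were 6, 0 higher and 6 lower. With an estimated correlation 5 lists passed, and by fry 9. Leaving out each array in turn gave 10 to 79 genes, 1 to 8 higher, 9 to 71 lower, 3 to 6 at least 2-fold apart, 17 to 21 lists, and a PDE2 difference from -2.086 to -1.849. Apart from fits with fewer arrays or genes, the cause was not tested.

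Among turned results, only arrays with DJ28 in Cy3 gave ADE1 -0.117, MET17 -0.005, URA3 -0.248, AGA2 -0.516, ASG7 -0.017, MF(ALPHA)1 0.300, MFA1 -0.210, MFA2 -0.186, STE3 0.127, STE6 -0.418, the cytosolic ribosomal list -0.321 (adjusted p = 5.05e-19) and the list specific to a or alpha cells -0.018. Only arrays with DJ28 in Cy5 gave ADE2 -0.096, the tricarboxylic acid cycle list 0.159 and the cell wall protein list -0.005, which turned in the camera test and not in its median. Fits on 1 dye orientation have no dye term, so these values hold the dye effect along with the strain difference. No centring gave MF(ALPHA)1 0.038 and STE3 0.088, no dye term gave STE3 0.011, and array weights gave ADE2 -0.012. All 10 arrays apart gave STE6 -0.066. The arrays with values at the upper limit gave ADE2 -0.024 and HIS3 -0.004, and the others gave MF(ALPHA)1 0.082, STE3 0.093 and STE6 -0.241. Without arrays 6 and 7, MF(ALPHA)1 was 0.072 and STE3 0.037, and without arrays 1 and 2, ADE2 was -0.021. Leaving out each array in turn gave ADE2 from -0.047 to 0.075, MF(ALPHA)1 from -0.310 to 0.155 and STE3 from -0.048 to 0.087. Apart from the dye effect held in the fits on 1 orientation, the cause was not tested.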

Other observations

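Hexose transporters and glucose sensing genes had 0 of 23 members past limma's test and 20 negative differences, with a median of -0.23 (camera adjusted p = 1.22e-05, and adjusted p = 0.155 with an estimated correlation), and -0.32 and -0.08 within the array sets, where the remaining arrays alone gave no call (adjusted p = 0.193). Genes of multidrug transport and weak-acid stress had 0 of 20 members past the test and 5 lower adjusted over the list alone, with a median of -0.21 (camera adjusted p = 9.58e-05, and adjusted p = 0.155 with an estimated correlation), and -0.28 and -0.10 within the array sets, and the call was lost with only the arrays that had DJ28 in Cy3 (-0.017, adjusted p = 0.485). In the tricarboxylic acid cycle, ACO1, which encodes aconitase, alone of 20 members fell over all genes tested, by 0.64 on the log2 scale (adjusted p = 0.0181, lower on 9 of 9 replicates), and 3 fell adjusted over the list alone. That list had a median of -0.07 (camera adjusted p = 0.00261, and adjusted p = 0.357 with an estimated correlation), and -0.15 and -0.07 within the array sets. It was -0.045 without array 3, -0.125 without array 4, -0.118 without array 5, -0.157 without array 8 and -0.145 without arrays 6 and 7 together, and above 0 with only the arrays that had DJ28 in Cy5, at 0.159. The call was lost with no centring (-0.047, adjusted p = 0.0637) and within the remaining arrays alone (adjusted p = 0.0866). Ion transport and calcineurin signalling had 0 of 28 members past the test over all genes, 5 lower adjusted over the list alone and a median of -0.09 (camera adjusted p = 0.00418, and adjusted p = 0.357 with an estimated correlation), with -0.26 and -0.08 within the array sets, -0.16 without array 2 and -0.146 without array 4. Over 29 alternatives to the arrays, genes and fit used, its call was lost in 5, with adjusted p from 0.0681 to 0.376. Amino acid biosynthesis had 0 of 59 and a median of 0.14 (camera adjusted p = 0.00615, and adjusted p = 0.373 with an estimated correlation), with 0.04 and 0.21 within the array sets, and its call was lost without array 8 (median 0.109, adjusted p = 0.0983), with array weights (0.074, adjusted p = 0.055), within arrays 4, 5, 9 and 10 alone (adjusted p = 0.136) and with only the arrays that had DJ28 in Cy3 (0.004, adjusted p = 0.993). Among cell wall proteins YGP1 alone of 35 fell both over all genes tested and adjusted over the list alone, with a list median of -0.10 (camera adjusted p = 0.0187, and adjusted p = 0.572 with an estimated correlation) and medians of -0.12 and 0.04 within the array sets. Its call was lost without array 3 (-0.031, adjusted p = 0.174), array 9 (-0.025, adjusted p = 0.159) or array 10 (-0.086, adjusted p = 0.077), and over the 29 alternatives it was lost in 8 and turned in 1. Phospholipid synthesis had 0 of 24 past the test and 2 lower adjusted over the list alone, with a median of -0.085 (camera adjusted p = 0.0173, lost with adjusted p = 0.357 with an estimated correlation), and -0.19 and 0.08 within the array sets. It lost its call without array 4 (median 0.007, adjusted p = 0.0695) or array 9 (-0.006, adjusted p = 0.0656), and its median was -0.015 without array 5. Over the 29 alternatives the call was lost in 8.

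Of the 43 lists, 22 did not pass camera with the preset correlation. In the list of vacuolar ATPase and vacuolar proteases PRB1, which encodes vacuolar proteinase B, alone of 22 members fell over all genes tested, by 0.78 on the log2 scale (adjusted p = 0.0435, lower on 8 of 8 replicates), and 3 fell adjusted over the list alone, while the list median was 0.04 and the test pointed lower (camera adjusted p = 0.162). The respiratory chain and ATP synthase list had a median of 0.15 (camera adjusted p = 0.0906) and, like the cytosolic ribosomal proteins, list medians of opposite sign in the dye orientations, -0.34 with DJ28 in Cy3 and 0.59 with DJ28 in Cy5. Glycolysis and fermentation had 0 of 20 members past limma's test and a median of 0.01 (camera adjusted p = 0.387). YCL042W, an open reading frame of unknown function that belongs to no list, was lower at -0.80 with a standard error of 0.141 (adjusted p = 0.0386, lower on 8 of 8 replicates).

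Lists that share members were tested apart, in subsets chosen after the data were seen. Without storage members the stress list had a median of -0.28 (camera adjusted p = 1.89e-12, and adjusted p = 0.000125 with an estimated correlation), and without stress members the storage list had a median of -0.41 (camera adjusted p = 8.69e-11, and adjusted p = 0.00568 with an estimated correlation). The osmotic and glycerol list without stress members had a median of -0.20 (camera adjusted p = 0.000189, and adjusted p = 0.0859 with an estimated correlation).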
